A study of Homo sapiens with 16 samples.

How the data were processed

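Poly(A) RNA of 3 cancer cell lines was measured by RNA-seq on an Ion Torrent instrument in 16 libraries. Per the labels' protocols, RNA was extracted with TRI reagent, poly(A) RNA was purified with oligo(dT) beads and libraries were made with an Ion Total RNA-seq kit, although the molecule field of the labels reads total RNA. The values are read counts per gene symbol, and the authors' deposited count table gives 1 column per library and no normalization. Per the submitters' processing notes, FastQC 0.11.2, GSNAP (no version), SAMtools 0.1.19, Picard 1.129, HTSeq 0.6.1 and deepTools 2.2.2 were used with hg19 (GRCh37), and the deposited table names HTSeq's intersection-nonempty mode of counting. The annotation, the strand setting of the counting and the read filters are not given in the sources used here. Without the strand setting, reads of antisense genes cannot be told from those of their partners, and reads shared by close paralogs and histone genes may be split or dropped by the counting, so values of such genes are uncertain.

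Each library was placed in its group by the labels: 4 cell backgrounds (p53WT HCT116, p53KO HCT116, MCF7 and SJSA) by 2 treatments (0.2% DMSO or 10 µM Nutlin, 12 h), with 2 replicates each. All 16 columns of the table were matched to a sample by name. The labels do not say that replicates came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. Replicates differed beyond counting noise (chi-square per gene from 7.05 to 25.8) and had Spearman correlations of 0.988 to 0.997, so no library was treated as a duplicate. The first and second principal components of log2 CPM held 47.7% and 34.4% of the variance and separated the lines. The labels give each sample a batch number equal to its replicate number, so the numbers pair samples. As a check, deviations of same-numbered libraries of the same cells correlated at 0.12 to 0.436 over 8 pairs (median 0.232), against -0.04 to 0.167 over 20 pairs of different cells. Here p53WT and p53KO HCT116 counted as the same cells, and the 0.436 was between their DMSO libraries. Between DMSO and Nutlin the values were 0.171 in p53WT HCT116, 0.124 in p53KO HCT116, 0.279 in MCF7 and 0.120 in SJSA, which overlap those of different cells.

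Counts were analysed in R 4.3.3. Genes with enough counts in at least as many libraries as a group holds were kept by edgeR 4.0.16 (filterByExpr), which left 18358 of 25369 genes, 23676 of which had any count. Library sizes were scaled by TMM factors, and edgeR's quasi-likelihood test was fitted to all 16 libraries in 8 groups with 8 residual degrees of freedom and no batch term. The biological coefficient of variation was 11.3%. Calls were made at a Benjamini-Hochberg adjusted p below 0.05 in each comparison. The comparisons were Nutlin against DMSO in each line, the difference of that effect between p53WT and p53KO HCT116 and between each pair of lines with intact TP53, and p53WT against p53KO HCT116 under DMSO. Genes called in the same direction in p53WT HCT116, MCF7 and SJSA were counted and set beside the number that independent lists would share. Lists from the same fit are not independent, so that number is a low reference. The SE of a log2 fold change was taken from the F statistic. CPM values of single genes use the TMM-scaled library sizes. Sums and medians over a list, and the levels compared in the checks on silent genes, neighbouring genes and mixed cells, use library totals. A fold against a group with 0 counts is given as a lower bound against 3 counts over that group's libraries together, and for groups with 1 to 3 counts only levels are given. Bounds cover counting error only. The binomial intervals treat genes as independent draws, which genes regulated together are not, and cover no spread between libraries.

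The gene lists were fixed before the data were examined, as were the comparisons, the main design, the rule for named genes and all alternative settings except those given below as added later. They held arrest and feedback targets of p53 (20 genes), apoptosis targets (22), metabolism and repair targets (22), replication genes of the G1/S step (30), G2/M and mitosis genes (32), homologous recombination (20), cholesterol synthesis (22), the unfolded protein and integrated stress response (22), interferon response (22), ribosomal proteins (40), ribosome biogenesis under MYC (24), estrogen response (20), NF-kB and inflammation (21), immediate early genes (19), replication-dependent histones (18, of which 16 were tested), mitochondrial mRNAs (13, of which 0 had a value), line markers of HCT116, MCF7 and SJSA (15 each) and leukocyte and erythroid markers (15, of which 8 were tested). Each was tested with camera in limma 3.58.1 on log2 CPM with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the lists of a comparison, and again with an estimated correlation. The correlation was estimated only from the fit without a batch term. Camera sets a list against all other tested genes, so a lost set call does not mean that its members did not change. Genes were named by a rule: TP53, MDM2 and CDKN1A everywhere, in each Nutlin comparison the 10 largest rises and 8 largest falls among called genes with at least 5 CPM in the higher group and the same direction in both batches, up to 4 members per list with the smallest p, the 15 genes per direction with the largest smallest change over the 3 lines with intact TP53, and the 6 largest differences per direction in the other comparisons. The text gives only part of the genes the rule named, and the rest are not reported here. List members named outside this rule, such as those that went against their list or made up a count of 5 or fewer, were chosen after their values were seen.

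The alternatives were RLE scaling, DESeq2 1.42.0, no filter on low counts, a fit to only the lines compared, the batch number as a block within HCT116, MCF7 and SJSA (replicate block, 5 residual degrees of freedom), and leaving out each library in turn, where the library left alone in its group was assumed to vary like the others. Upper-quartile scaling, scaling to library totals and thinning of all libraries to the smallest total were added after seeing the data. The tests were run first on simulated data with the real DMSO means and library sizes and known changes in 200 genes. The changed genes were drawn only from those above a minimum level. The shares recovered therefore do not cover genes at lower levels, nor data in which a large part of all genes changed. For Nutlin in p53WT HCT116, 53.7% of 1.5-fold, 88.1% of 2-fold and 96.97% of 4-fold changes were recovered among 17062 genes, with 12 false calls of 171. For p53KO HCT116 the shares were 61.2%, 91.0% and 98.5% among 17057 genes, for MCF7 53.7%, 82.1% and 100% among 17054, and for SJSA 49.3%, 71.6% and 95.5% among 17085. For the difference between p53WT and p53KO HCT116 they were 23.9%, 70.2% and 95.5% among 17053 genes, so small differences in effect were detected less often than small effects. Total counts ran from 27.4 to 54.6 in units of 1e6 per library, and 3 counts over a group's libraries corresponded to 0.0352 to 0.0495 CPM under DMSO. Gene order, strand and protein-coding status for a check on neighbouring genes in the closing section came from an annotation of GRCh38, a different assembly from that of the reads, so no positions are given.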

Results

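Poly(A) RNA of human cancer cell lines was sequenced after treatment with Nutlin, a small molecule that occupies the p53-binding pocket of MDM2, to ask which transcripts change when p53 is released, which of the changes need TP53 and how they vary with the line. HCT116 is a colorectal adenocarcinoma line and was used with intact TP53 (p53WT) and as a TP53 knockout (p53KO). MCF7 is a breast adenocarcinoma line and SJSA an osteosarcoma line known for an amplified MDM2 gene. Cells received 10 µM Nutlin or 0.2% DMSO, the solvent control, for 12 h, which gave 8 groups of 2 libraries and 16 libraries in all. Total counts in units of 1e6, replicates 1 and 2 in order, were 54.6 and 34.3 for p53WT HCT116 under DMSO and 39.0 and 31.0 under Nutlin, and 32.7 and 30.6 for p53KO HCT116 under DMSO and 37.0 and 29.9 under Nutlin. MCF7 gave 33.6 and 36.1 under DMSO and 29.8 and 27.4 under Nutlin, and SJSA 30.8 and 34.1 under DMSO and 32.9 and 30.5 under Nutlin. Of 25369 genes in the table, 18358 had enough counts to be tested. Genes are given by the symbols of the table, which carries no positions. The reads were aligned to hg19 (GRCh37). Levels below are means ± SD of CPM, counts scaled to 1e6 per library (n = 2), and changes are log2 fold changes ± SE from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (2 libraries against 2).

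TP53 itself, the gene removed in the knockout, was read first. It stood at 75.8 and 86.9 CPM in the libraries of p53WT HCT116 under DMSO and at 8.64 and 8.10 CPM in those of p53KO HCT116, a log2 difference of 3.28 ± 0.13 (adjusted p = 2.43e-13 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Under Nutlin the libraries held 90.5 and 80.7 CPM in p53WT HCT116 and 10.9 and 11.3 CPM in p53KO HCT116. The part of the gene that was deleted is not given in the sources used here. With Nutlin, TP53 mRNA fell in MCF7 from 171 ± 1.21 to 84.5 ± 13.1 CPM (log2 fold change -1.02 ± 0.11) and in SJSA from 108 ± 4.27 to 73.2 ± 2.35 CPM (-0.56 ± 0.11). The SJSA fall was -0.36 with median-ratio (RLE) scaling and -0.29 with upper-quartile scaling, the latter chosen after seeing the data, and passed the threshold with both. In p53WT HCT116 the value was 0.08 ± 0.11 and in p53KO HCT116 0.41 ± 0.13, and neither passed (adjusted p = 0.673 and 0.347 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The fixed marker lists of each line were read under DMSO as a second look at the labels. The 15 MCF7 markers, luminal breast genes such as ESR1 and GATA3, summed to 23480.0 CPM in MCF7, 4539 in p53WT HCT116 and 204 in SJSA, and the 15 mesenchymal SJSA markers, such as VIM and COL1A1, to 15700.0 CPM in SJSA and 53.6 to 188 CPM in the other lines. The 15 intestinal markers chosen for HCT116 did not single out that line, at 396 CPM in p53WT HCT116, 470.3 in MCF7 and 3.68 in SJSA.

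**Figure D1:**
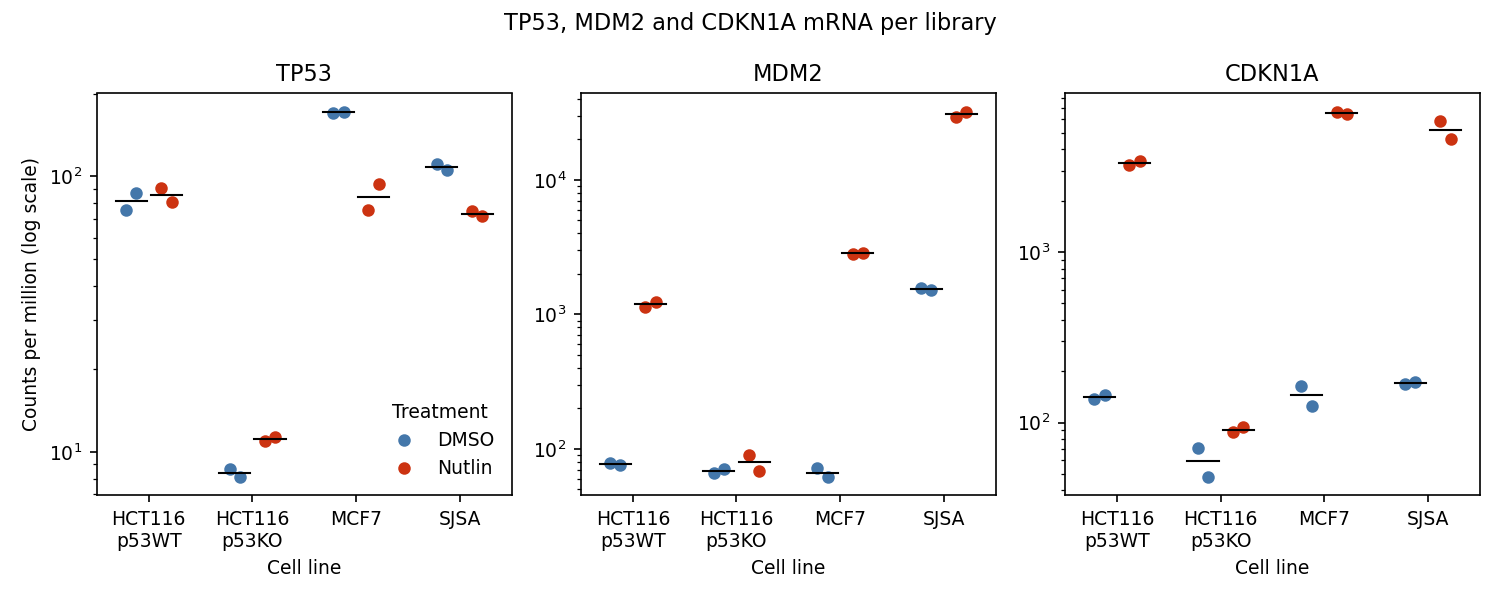
TP53, MDM2 and CDKN1A mRNA in CPM (log scale) for each of the 16 libraries, by line and treatment. Each point is 1 library. TP53 stayed at or below 11.3 CPM in the 4 p53KO HCT116 libraries, and MDM2 and CDKN1A were higher under Nutlin in both libraries of p53WT HCT116, MCF7 and SJSA.

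In p53WT HCT116, Nutlin raised p53 target genes and lowered genes of replication, mitosis and homologous recombination. CDKN1A, which encodes the cell cycle inhibitor p21, rose from 142 ± 4.91 to 3304 ± 125 CPM (4.54 ± 0.17), MDM2, which encodes the ubiquitin ligase that turns p53 over, rose from 77.1 ± 1.68 to 1185 ± 70.6 CPM (3.94 ± 0.13), and the antiproliferative gene BTG2 rose by 3.92 ± 0.14. Among the 10 steepest rises at 5 CPM or more were ABCA12, a lipid transporter of the epidermis (5.79 ± 0.28), SORCS2 (5.79 ± 0.48), TP53I3, a p53-induced oxidoreductase (4.91 ± 0.15), INPP5D (4.91 ± 0.23), the cholesterol exporter ABCA1 (4.67 ± 0.22), the stress cytokine GDF15 (4.42 ± 0.25), TP53INP1 (4.30 ± 0.21) and GRHL3, a transcription factor of epidermal differentiation (4.27 ± 0.42). The steepest falls included ZNF367 (-2.79 ± 0.18), CCNE2, which encodes a cyclin of the G1/S step (-2.67 ± 0.19), DTL (-2.53 ± 0.16), E2F2 (-2.38 ± 0.17), CLSPN (-2.19 ± 0.14), FBXO5 (-2.19 ± 0.16) and MCM10 (-2.17 ± 0.13). In all 2360 genes rose and 2570 fell, 842 and 408 of them at least 2-fold. Scaling to library totals, chosen after seeing the data, put 64.4% of the called genes among those that rose, in place of 47.9%. Leaving out the DMSO library of replicate 1 gave 1566 genes that rose and 1541 that fell, and leaving out the Nutlin library of replicate 2 gave 1464 that rose, with the count that fell at 60.9% of its value with all libraries.

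By gene list, 18 of 20 arrest and feedback targets of p53 rose in p53WT HCT116 and 0 fell (19 and 0 adjusted over the list alone), and E2F7 and CABLES1 did not pass. Of 22 apoptosis targets 16 rose, such as BBC3, which encodes PUMA (3.24 ± 0.16), the death receptor gene TNFRSF10B (1.72 ± 0.10) and APAF1 (1.99 ± 0.13), and BID fell by 0.31 (16 and 2 adjusted over the list alone and with the replicate block). Of 22 metabolism and repair targets 19 rose and 0 fell (19 and 1 adjusted over the list alone, 20 and 1 with the block), with SESN1 at 3.18 ± 0.12, CYFIP2 at 2.52 ± 0.11, FDXR at 2.91 ± 0.13 and RRM2B, a ribonucleotide reductase subunit gene, at 2.26 ± 0.11. Replication genes of the G1/S step fell in 28 of 30 cases and rose in 0 (29 and 0 adjusted over the list alone), with TYMS and PCNA not passing. All 32 G2/M genes fell (also adjusted over the list alone), such as CDC25A (-2.15 ± 0.13), CCNA2 (-2.02 ± 0.14) and CCNB1 (-1.80 ± 0.14). Homologous recombination genes fell in 19 of 20 cases (20 adjusted over the list alone), with BRCA1 at -1.49 ± 0.12, RAD51 at -1.81 ± 0.15 and EXO1 at -2.14 ± 0.20. These 6 lists moved as sets in camera tests with Benjamini-Hochberg adjustment over the 19 lists tested (adjusted p from 0.00104 to 0.0462 with an estimated correlation). Ribosome biogenesis genes driven by MYC fell in 13 of 24 cases and rose in 0 (15 and 0 adjusted over the list alone), among them NOLC1 (-0.64 ± 0.11) and NCL (-0.69 ± 0.12), and 8 fell with library totals. This set's call (camera adjusted p = 1.94e-04) was lost at an adjusted p = 0.488 with an estimated correlation.

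No other list moved as a set in p53WT HCT116 by camera. Of 22 cholesterol synthesis genes 6 fell, led by DHCR24 (-0.96 ± 0.11), and LSS, HSD17B7 and TM7SF2 (1.71 ± 0.18) rose (7 and 3 adjusted over the list alone). In the unfolded protein and integrated stress response list, DDIT4 (3.15 ± 0.21), ATF3 (1.11 ± 0.17), EDEM1 and CEBPB rose among 22 (4 adjusted over the list alone), while the replicate block gave 6 rises and 4 falls. CEBPB stood at 0.45 ± 0.12 and its call was lost without the DMSO or the Nutlin library of replicate 1 (0.38 and 0.36). Interferon genes split, with 5 of 22 rising, such as the double-stranded RNA sensor TLR3 (2.68 ± 0.32), and OAS2 and OAS3 falling (6 and 3 adjusted over the list alone). Of 19 immediate early genes 4 rose and 6 fell (5 and 6 adjusted over the list alone), with KLF4 at -0.55 ± 0.12. NR4A1 fell by 1.17 and FOS by 1.09, and both calls were lost without the DMSO library of replicate 2 (-0.52 and -0.60), the FOS call also without the Nutlin library of replicate 2 (-0.77). In the NF-kB list 4 of 21 rose, led by ICAM1 (1.64 ± 0.27), and NFKBIA fell by 0.61 (4 and 1 adjusted over the list alone, 4 and 3 with the block). In the estrogen response list 2 of 20 rose, AREG (1.84 ± 0.21) and GREB1 (0.76 ± 0.15), and MYB, NRIP1 and SIAH2 fell (2 and 3 adjusted over the list alone, 3 and 5 with the block). The falls of MYB and SIAH2 were lost without the Nutlin library of replicate 2 (-1.27 and -0.39). Among 40 ribosomal protein genes only RPL3 passed, at 0.34 (0 adjusted over the list alone, 3 with the block), a call lost without the DMSO library of replicate 1 (0.35) or the Nutlin library of replicate 2 (0.32). Replication-dependent histone genes were read from poly(A) RNA, and HIST1H1E (-1.54 ± 0.33) and HIST2H2BE fell among 16 tested (2 adjusted over the list alone). The HIST2H2BE fall was lost without the Nutlin library of replicate 1 (-1.27). Among line markers EPCAM (-0.60 ± 0.11) fell, KRT19 (0.64 ± 0.11) and GREB1 rose, and FN1 fell by 0.63 and COL1A1 rose by 0.47. The COL1A1 call was lost without the DMSO library of replicate 1 (0.21) or the Nutlin library of replicate 2 (0.38) and with only the lines compared (0.501), and its value was 0.80 without the DMSO library of replicate 2. Adjusted over the list alone, 1 HCT116, 2 MCF7 and 2 SJSA markers passed, and with the block 3 SJSA markers rose and 1 fell, and 2 MCF7 markers rose and 1 fell. Of the 8 leukocyte and erythroid markers tested 0 passed in edgeR, over all genes or adjusted over the list alone, 0 had an unadjusted p under the threshold and 0 passed in DESeq2, while 1 fell with the block. The summed level of all 15 markers of that list was 26.2 CPM under DMSO and 23.3 under Nutlin. The mitochondrial list could not be read, since 0 of its 13 genes had a value in the table.

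In MCF7 the same p53 target lists rose and the cell cycle lists fell. MDM2 rose from 66.8 ± 7.11 to 2842 ± 19.8 CPM (5.41 ± 0.14), CDKN1A from 145 ± 26.8 to 6541 ± 133 CPM (5.50 ± 0.18), the death receptor gene FAS from 2.01 ± 1.08 to 173 ± 34.6 CPM (6.44 ± 0.23) and TP53I3 by 6.42 ± 0.16. Large rises were found in genes nearly silent under DMSO. CLCA2, a p53-inducible epithelial gene, rose from 0.0578 ± 0.0433 to 89.9 ± 25.2 CPM (10.54 ± 0.46) and the transcription factor gene NHLH2 by 8.45 ± 0.42, while LCE1B, a late cornified envelope gene, had 0 counts under DMSO and 18.1 ± 8.79 CPM under Nutlin, at least 428-fold higher against a floor of 3 counts over both DMSO libraries. LCE1E, CCDC60, NODAL and FLG-AS1 also started from 0 counts, with bounds of at least 242, 131, 122 and 163-fold. LCE1B and LCE1E are close paralogs and FLG-AS1 is antisense to another gene, so their counts are uncertain. The largest falls were in FAM111B (-6.67 ± 0.25), the helicase gene PIF1 (-6.32 ± 0.30), the kinetochore gene NDC80 (-6.22 ± 0.24), FAM64A (-6.07 ± 0.20) and MCM10 (-5.74 ± 0.18). In all 3829 genes rose and 4673 fell, 2114 and 1754 of them at least 2-fold. With upper-quartile scaling, chosen after seeing the data, 55.3% of the called genes rose, in place of 45.0%.

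Of the p53 lists in MCF7, 19 of 20 arrest genes, 17 of 22 apoptosis genes and 20 of 22 metabolism and repair genes rose, and BID and SCO2 fell. Examples are ZMAT3 (3.80 ± 0.11), SESN1 (3.69 ± 0.12) and the translesion polymerase gene POLH (3.05 ± 0.11). Replication genes fell in 29 of 30 cases, all but PCNA, as did all 32 G2/M genes and all 20 homologous recombination genes, and none of these rose. Adjusted over the list alone, the counts of these 6 lists were unchanged. Their set calls held by camera with Benjamini-Hochberg adjustment (adjusted p from 0.00412 to 0.0461 with an estimated correlation). Ribosome biogenesis genes fell in 22 of 24 cases (22 adjusted over the list alone), with NOLC1 at -2.26 ± 0.12 (camera adjusted p = 8.26e-11, and adjusted p = 0.136 with an estimated correlation). Of 19 immediate early genes 13 rose, led by FOSL1 (5.09 ± 0.23) and KLF4 (1.88 ± 0.11), and MYC fell by 1.56 (13 and 1 adjusted over the list alone). The set call (camera adjusted p = 7.49e-05) was lost at an adjusted p = 0.297 with an estimated correlation. Cholesterol synthesis genes rose in 11 of 22 cases, such as FDFT1 (0.90 ± 0.09), with DHCR7 and DHCR24 falling (11 and 2 adjusted over the list alone, 11 and 4 with the block), and stress response genes rose in 10 of 22, such as ATF3 (3.10 ± 0.21), with SDF2L1 falling (11 and 2 adjusted over the list alone, 12 and 4 with the block). Both set calls (camera adjusted p = 0.0269 and 0.0367) were lost at an adjusted p = 0.460 with an estimated correlation. In the NF-kB list 8 of 21 rose, with NFKBIA at 1.75 ± 0.13, and NFKB2 and SOD2 fell (8 and 2 adjusted over the list alone). Its camera adjusted p was 0.0532, and 0.0280 with the replicate block (without the block, adjusted p = 0.451 with an estimated correlation). Estrogen response genes went both ways, 6 of 20 up and 5 down (6 and 5 adjusted over the list alone), with the estrogen receptor gene ESR1 at -0.60 ± 0.14 and CXCL12 at -2.34 ± 0.19. Foreign markers moved too. Of 8 leukocyte markers tested ITGAM (2.45 ± 0.45) and CD68 rose (2 adjusted over the list alone), and CD68 was lost without the Nutlin library of replicate 1 (0.46 in place of 0.99). The sum over all 15 markers of that list went from 6.67 to 19.7 CPM. Among markers of the other lines, 6 of 15 of the intestinal and 6 of 15 of the mesenchymal list rose and 2 of each fell, with COL6A3 at 3.44 ± 0.24, and the same counts were found adjusted over the list alone.

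In SJSA more genes changed than in p53WT HCT116 or MCF7. Most p53 target genes rose and most cell cycle genes fell, but 5 of the 6 set calls were lost here (camera adjusted p from 0.128 to 0.230 with an estimated correlation). Camera set each list against all other tested genes, and 63.9% of tested genes were called in SJSA. MDM2, already at 1537 ± 30.6 CPM under DMSO, rose to 30800.0 ± 1778 CPM (4.33 ± 0.13) and made up 2.83% and 3.19% of all counts in the Nutlin libraries. CDKN1A rose from 171 ± 4.08 to 5198 ± 892 CPM (4.93 ± 0.17), GDF15 by 5.96 ± 0.27, BTG2 by 5.02 ± 0.15 and BBC3 by 4.13 ± 0.17. Large rises were again found in genes without counts under DMSO, for which only lower bounds can be given. LAD1, which encodes the basement membrane protein ladinin, had 0 counts under DMSO and 35.1 ± 8.01 CPM under Nutlin, at least 789.7-fold higher, TNNT2 at least 446-fold, IGFL3 378-fold, the brush border myosin gene MYO1A 360.3-fold and the amino acid transporter gene SLC6A19 258-fold, each against the floor of 3 counts over both DMSO libraries. CELA2A also rose from 0 counts (at least 326-fold), but shares sequence with CELA2B, so its counts are uncertain. Among the steepest falls were NXPH2 (-5.08 ± 0.68), SPSB4 (-4.30 ± 0.56), JAKMIP2 (-4.24 ± 0.58), SSX2IP (-4.09 ± 0.18) and DHRS13 (-4.07 ± 0.30). In all 5291 genes rose and 6437 fell, 3432 and 3232 of them at least 2-fold. The split depended on scaling. Of the called genes 45.1% rose with TMM, 55.3% with RLE and 59.2% with upper-quartile scaling, and the median of all genes was -0.07, 0.13 and 0.20, the last scaling chosen after seeing the data.

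The p53 lists in SJSA rose in 18 of 20 arrest, 16 of 22 apoptosis and 18 of 22 metabolism and repair genes, with CYFIP2 at 3.77 ± 0.12 and FDXR at 3.94 ± 0.14. CABLES1, SCO2 and 5 apoptosis genes (CASP6, SHISA5, TNFAIP8, TP53BP2 and BID) fell. G1/S genes fell in 29 of 30 cases, all 32 G2/M genes fell, such as CCNA2 (-3.05 ± 0.15), and 18 of 20 homologous recombination genes fell, with BRCA2 and PALB2 not passing. Counts adjusted over the list alone were the same for these 6 lists. Only the metabolism and repair list kept its camera call, with Benjamini-Hochberg adjustment (adjusted p = 0.0260 with an estimated correlation). The other 5 had camera adjusted p of 1.63e-04 or less with the preset correlation, against the values from 0.128 to 0.230 with an estimated correlation given above. Ribosomal protein genes rose in 38 of 40 cases and 0 fell (39 and 0 adjusted over the list alone), with RPS19 at 1.05 ± 0.15, RPLP2 at 0.61 ± 0.09 and RPL11 at 0.58 ± 0.09. Every scaling gave 34 to 40 rises and 0 falls, against the median shifts above. The set call (camera adjusted p = 7.26e-07) was lost at an adjusted p = 0.408 with an estimated correlation. Ribosome biogenesis genes fell in 12 of 24 cases and rose in 3 (12 and 3 adjusted over the list alone). This set did not pass (camera adjusted p = 0.216, and adjusted p = 0.733 with an estimated correlation). Immediate early genes rose in 12 of 19 cases, such as EGR3 (4.32 ± 0.47), with DUSP1 and NR4A1 falling (12 and 2 adjusted over the list alone, camera adjusted p = 0.0298 and adjusted p = 0.50 with an estimated correlation). Stress response genes rose in 12 of 22 cases, such as the chaperone gene HSPA5 (1.11 ± 0.13), and 5 fell (13 and 7 adjusted over the list alone), with a camera adjusted p of 0.0934, or 0.0482 with the replicate block (without the block, adjusted p = 0.597 with an estimated correlation). Cholesterol synthesis genes fell in 11 of 22 cases, led by DHCR24 (-1.50 ± 0.11), and 3 rose (also adjusted over the list alone), or 6 and 4 with RLE. Interferon genes fell in 9 of 22 cases, such as IFIT1 (-3.47 ± 0.51), and ISG20 (2.30 ± 0.31), STAT2 and TLR3 rose (9 and 3 adjusted over the list alone), or 7 and 5 with RLE and 10 and 5 with the block. Markers foreign to the line moved from low levels. Of 15 intestinal markers 8 rose and LGR5 fell (8 and 1 adjusted over the list alone), VIL1 going from 0.0140 to 7.12 CPM (1 and 438 counts), and their sum from 3.68 to 19.7 CPM (camera adjusted p = 0.00708, and adjusted p = 0.128 with an estimated correlation). Of the 15 luminal markers 5 rose, such as GREB1 (from 3.12 ± 0.488 to 53.3 ± 6.64 CPM), and FOXA1, KRT18 and PGR fell (5 and 3 adjusted over the list alone, camera adjusted p = 0.340), and their median level went from 2.38 to 0.854 CPM. Of the 15 mesenchymal markers of SJSA itself ALPL, COL6A3, FN1 and SPARC rose, and CDH11, THY1, TWIST1 and ZEB1 fell (4 and 4 adjusted over the list alone, camera adjusted p = 0.855), and their sum went from 15700.0 to 16650.0 CPM. With upper-quartile scaling 7 of these rose. The COL6A3 call (0.47) was lost without either DMSO library (0.44 in both) or the Nutlin library of replicate 2 (0.41), and the SPARC call (0.57) without the DMSO library of replicate 2 (0.35). Of 8 leukocyte markers tested CD79A (4.51 ± 0.62), ITGAM (2.40 ± 0.43), CD19 and LYZ rose and CD2 fell (4 and 1 adjusted over the list alone). The sum over all 15 markers of that list went from 92.6 to 133 CPM. LYZ had 0 counts under DMSO and 0.422 CPM under Nutlin, at least 9.49-fold higher, and its call was lost in DESeq2.

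In p53KO HCT116, Nutlin changed 33 genes, of which 24 rose and 9 fell. DDIT4, an mTOR inhibitor gene of the stress response, rose from 7.33 ± 0.104 to 32.6 ± 12.4 CPM (2.15 ± 0.22), the metallothionein gene MT1E from 245 ± 36.8 to 534 ± 51.3 CPM, GDF15 by 1.61 ± 0.26, the glutathione-degrading enzyme gene CHAC1 by 2.31 ± 0.44 and BTG2 by 1.00 ± 0.14. The potassium channel gene KCNJ2 fell from 118 ± 2.98 to 26.4 ± 4.68 CPM (-2.16 ± 0.12), as did the zinc exporter gene SLC30A1 (-1.91 ± 0.19) and the circadian repressor genes NR1D1 (-1.35 ± 0.19) and NR1D2 (-1.29 ± 0.15). MDM2 was at 0.22 ± 0.12 and CDKN1A at 0.61 ± 0.15, neither past the threshold (adjusted p = 0.693 and 0.13 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). With the replicate block CDKN1A passed (adjusted p = 0.00339 in edgeR). Without the filter, with other tools or with the block more genes passed. DESeq2 called 77 up and 46 down and the replicate block 117 and 78, each with all 33 genes of the main test among them, and 1436 genes had an unadjusted p under 0.05 in edgeR. Leaving out single libraries gave 2 to 15 rises and 3 to 5 falls. GDF15 was lost without the DMSO or the Nutlin library of replicate 2 (1.17 and 1.57), BTG2 without the same libraries (0.95 and 0.92), CHAC1 without the DMSO library of replicate 1 (1.82) or the Nutlin library of replicate 2 (1.53), and NR1D1 without the latter (-1.33). Of the 24 genes that rose, 19 also rose in p53WT HCT116, 16 in MCF7 and 15 in SJSA, against 3.09, 5.01 and 6.92 for independent lists. Of the 9 that fell, 5, 2 and 3 also fell there, against 1.26, 2.29 and 3.16. These lists came from the same fit, so they are not independent and the numbers are a low reference.

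Among the lists in p53KO HCT116, the stress response genes DDIT4, CHAC1 and TRIB3 rose of 22 (7 and 0 adjusted over the list alone, camera adjusted p = 2.69e-05, and adjusted p = 0.418 with an estimated correlation), and 7 rose with the replicate block. BTG2 and GDF15 rose of 20 arrest targets (5 and 1 adjusted over the list alone and with the block) and SESN2 and FDXR of 22 metabolism and repair targets (6 and 1 adjusted over the list alone, 4 and 0 with the block). Both sets had a camera adjusted p of 2.02e-04, lost with an estimated correlation (adjusted p = 0.418 and 0.177 with an estimated correlation). BBC3 and APAF1 rose of 22 apoptosis targets (3 and 1 adjusted over the list alone), and ZFP36 of 19 immediate early genes (4 and 0 adjusted over the list alone, 3 with the block). The calls of APAF1 (0.63 to 0.72), FDXR (0.61 to 0.71) and ZFP36 (0.72 to 1.00) were lost without any 1 of the 4 libraries compared. Those of BBC3, SESN2 and TRIB3 were lost without either DMSO library or without the Nutlin library of replicate 2, where they stood at 0.51, 0.51 and 0.48, and that of BBC3 also with only the lines compared (0.90). In edgeR 0 of 30 G1/S, 0 of 32 G2/M and 0 of 20 homologous recombination genes passed, also adjusted over the list alone, 0 of them had an unadjusted p under the threshold, and DESeq2 called 0. The G1/S and G2/M sets and the ribosome biogenesis set shifted down by camera (adjusted p = 0.00704, 0.0103 and 4.72e-06), calls lost with an estimated correlation (adjusted p = 0.705, 0.705 and 0.422 with an estimated correlation), with ribosome biogenesis at 0 and 4 adjusted over the list alone, 0 and 2 with the block, 7 of 24 genes lower at an unadjusted p under the threshold and 0 called by DESeq2. The HCT116 marker and ribosomal protein sets also shifted down (camera adjusted p = 0.00971 and 0.0157), calls lost with an estimated correlation (adjusted p = 0.195 and 0.705 with an estimated correlation). In edgeR 0 genes of either passed, also adjusted over the list alone, 2 of the 15 markers and 0 of the 40 ribosomal protein genes were lower at an unadjusted p under the threshold, and DESeq2 called 0.

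**Figure D2:**
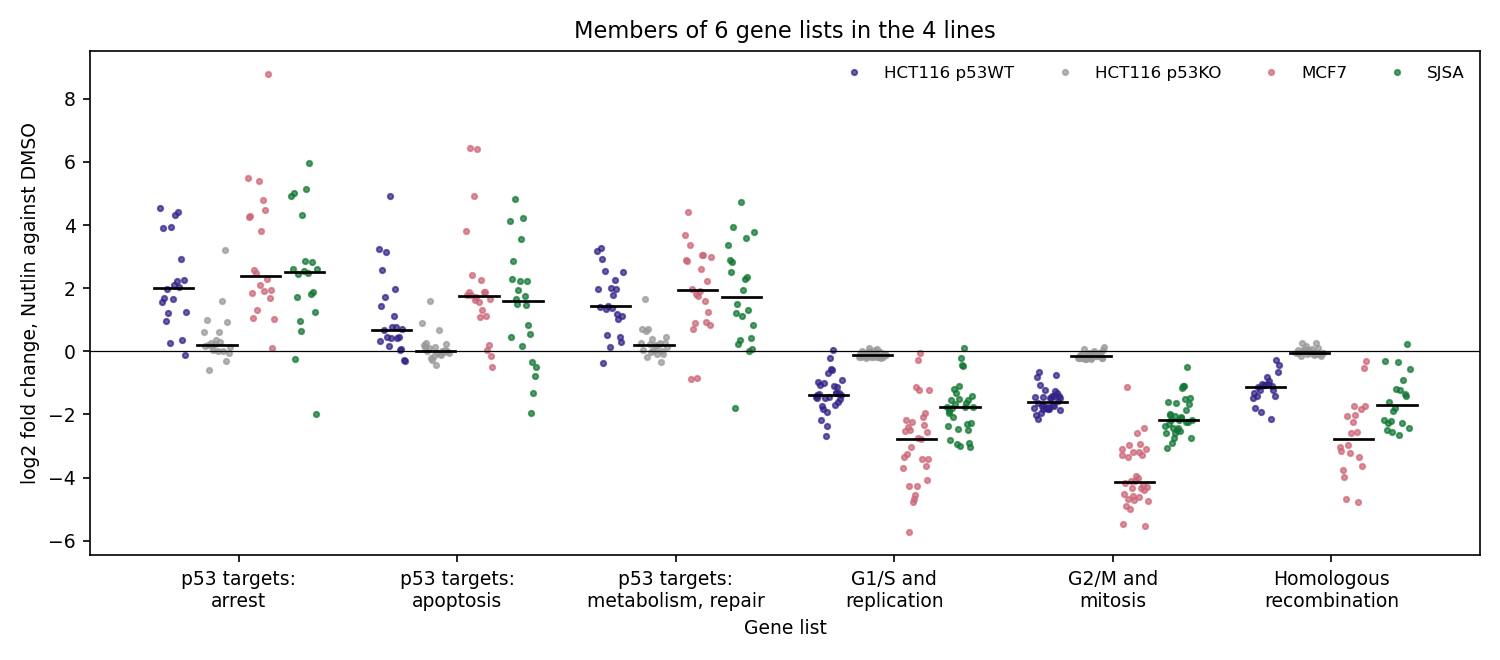
log2 fold changes, Nutlin against DMSO, of the members of 6 gene lists in the 4 lines. Each point is 1 gene of a list in 1 line. The 32 G2/M genes fell in p53WT HCT116, MCF7 and SJSA, and 0 of them passed the test in p53KO HCT116.

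Whether the Nutlin response depended on TP53 was tested by the difference in effect between p53WT and p53KO HCT116. Only 1 knockout line was used, and 846 genes differed between the lines under DMSO. Loss of TP53 therefore cannot be told apart here from other differences between these lines. The effect was higher in p53WT cells for TP53I3 (5.04 ± 0.21), CDKN1A (3.93 ± 0.22), MDM2 (3.72 ± 0.17), WDR63 (3.84 ± 0.59) and BTG2 (2.91 ± 0.19), and lower for CCNE2 (-2.77 ± 0.26), ZNF367 (-2.72 ± 0.24), DTL (-2.41 ± 0.21), E2F2 (-2.20 ± 0.24), WDR76 (-2.20 ± 0.23) and FAM111B (-2.14 ± 0.24). UNC5B-AS1 (5.09 ± 0.88) and CEACAM1 (4.53 ± 0.90) were also higher, but were lost without p53KO DMSO replicate 2 (3.66) and p53KO DMSO replicate 1 (1.98), respectively, and the first is an antisense gene whose reads cannot be told from those of its partner here. Of the p53 lists 17 of 20 arrest, 12 of 22 apoptosis and 16 of 22 metabolism and repair genes had the higher effect in p53WT cells and 0 the lower (17, 13 and 18 adjusted over the list alone). Of the G1/S, G2/M and homologous recombination lists 26 of 30, 31 of 32 and 18 of 20 had the lower and 0 the higher (28, 32 and 19 adjusted over the list alone). All 6 held by camera with Benjamini-Hochberg adjustment (adjusted p from 4.98e-04 to 0.0365 with an estimated correlation). In all the effect was higher in p53WT cells for 666 genes and lower for 801, or 1092 and 1328 with the replicate block. Which direction held more genes turned with scaling, at 749 higher and 676 lower with RLE, 774 and 660 with upper-quartile scaling and 758 and 628 with library totals. Without p53KO Nutlin replicate 1 the counts were 421 and 491, and without p53WT Nutlin replicate 2 the lower count was 466. For TP53 the difference was -0.33 ± 0.17, which did not pass (adjusted p = 0.289 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Of the 24 genes that rose in p53KO cells 14 differed in effect between both, and of the 9 that fell 3 did. For DDIT4 the effect was higher in p53WT cells by 1.00 ± 0.30, a call lost in DESeq2 (1.03), with only the lines compared (1.03), and without p53WT DMSO replicate 1 (0.80), p53WT Nutlin replicate 2 (0.71), p53KO DMSO replicate 1 (0.98), p53KO DMSO replicate 2 (1.01) or p53KO Nutlin replicate 1 (0.65).

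**Figure D3:**
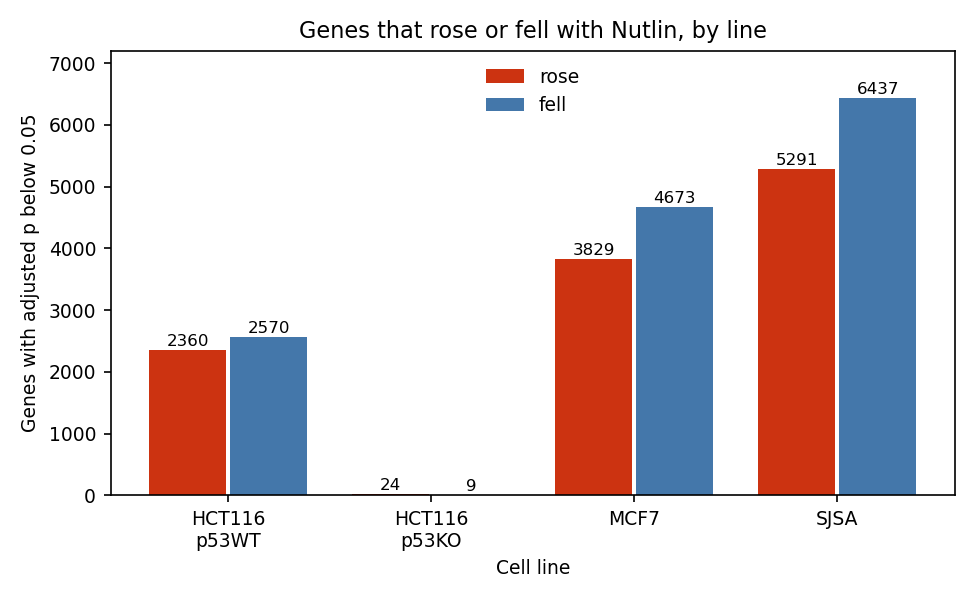
Number of genes that rose or fell with Nutlin in each line at an adjusted p below 0.05 in edgeR's quasi-likelihood test. The bars show 2360 and 2570 genes for p53WT HCT116, 3829 and 4673 for MCF7, 5291 and 6437 for SJSA, and 24 and 9 for p53KO HCT116.

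The lines with intact TP53 differed in the size of the response, tested as a difference in Nutlin effect. Against p53WT HCT116, MCF7 had the larger rise of MDM2 (difference 1.47 ± 0.16), CDKN1A (0.95 ± 0.21), FAS (3.88 ± 0.28) and GADD45A (2.70 ± 0.19), the deeper fall of CDK1 (-3.70 ± 0.21), MCM10 (-3.57 ± 0.23) and TP53 (-1.09 ± 0.16), and a higher effect on the limb transcription factor gene TBX4 (8.37 ± 0.75) and on FOSL1 (5.74 ± 0.29). G2/M genes fell further in MCF7 in 31 of 32 cases (32 adjusted over the list alone) and G1/S genes in 27 of 30 (28 adjusted over the list alone), set calls lost with an estimated correlation (adjusted p = 0.0765 with an estimated correlation for both). For ribosome biogenesis 21 of 24 genes fell further (21 adjusted over the list alone, adjusted p = 0.180 with an estimated correlation). Of p53 apoptosis genes 13 of 22 rose further in MCF7 and APAF1 less (16 and 1 adjusted over the list alone, adjusted p = 0.0765 with an estimated correlation). Between SJSA and p53WT HCT116, MDM2 and CDKN1A did not differ past the threshold (0.38 ± 0.16 and 0.38 ± 0.21, adjusted p = 0.0590 and 0.145 in edgeR's quasi-likelihood test), but did with the replicate block (adjusted p = 0.00838 and 0.0476 in edgeR). TP53 differed by -0.64 ± 0.16 (-0.41 with upper-quartile scaling), NXPH2 by -5.75 ± 1.18, the p53 target AEN by 2.05 ± 0.14 and the death receptor gene TNFRSF10A by 4.16 ± 0.34. Ribosomal protein genes had the higher effect in SJSA in 28 of 40 cases and the lower in 0 (31 and 0 adjusted over the list alone, adjusted p = 0.697 with an estimated correlation), or 15 and 0 with library totals. Against MCF7, the effect in SJSA was lower for MDM2 (-1.09 ± 0.16) and CDKN1A (-0.57 ± 0.21) and higher for TP53 (0.45 ± 0.16). The CDKN1A call was lost with RLE and DESeq2 (-0.49 in both), with upper-quartile scaling (-0.43) and without MCF7 DMSO replicate 2 (-0.42), SJSA DMSO replicate 2 (-0.57) or SJSA Nutlin replicate 2 (-0.38). The TP53 call was lost with library totals (0.36) and without MCF7 DMSO replicate 1 (0.44) or 2 (0.42), MCF7 Nutlin replicate 1 (0.28), SJSA DMSO replicate 1 (0.47) or 2 (0.39) or SJSA Nutlin replicate 1 (0.43). G2/M genes had the higher effect, a smaller fall, in SJSA than in MCF7 in 30 of 32 cases, with CDC25B lower (30 and 1 adjusted over the list alone, adjusted p = 0.420 with an estimated correlation). In all 4204 genes differed between MCF7 and p53WT HCT116, 8013 between SJSA and p53WT HCT116 and 8028 between SJSA and MCF7. The share with the higher effect in the first line was 38.8%, 39.4% and 44.5%. With RLE the first shares were 49.4% and 51.5%, with library totals 27.3% and 28.2%, and with upper-quartile scaling the share was 54.96% between SJSA and p53WT HCT116 and 54.15% between SJSA and MCF7.

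The response common to the 3 lines with intact TP53 held 816 genes that rose in each and 1465 that fell in each, against 142 and 229 for independent lists. The balance of directions depended on scaling, with 1033 rises and 1101 falls shared with RLE and 1136 and 993 with upper-quartile scaling. The 3 comparisons have no library in common, but they were tested in the same fit with a shared estimate of the spread. A gene with a low spread or many counts is thus more easily called in each line. The numbers for independent lists are therefore a low reference. CDKN1A rose by 4.54, 5.50 and 4.93 in p53WT HCT116, MCF7 and SJSA, GDF15 by 4.42, 4.49 and 5.96, TP53INP1 by 4.30, 4.79 and 5.14, and ABCA12 by 5.79, 6.28 and 6.10. CCNE2 had changes of -2.67, -4.78 and -2.94, the checkpoint adaptor gene CLSPN of -2.19, -4.73 and -2.48, the centromere chaperone gene HJURP of -2.08, -4.72 and -2.17, the mitotic kinase gene PLK1 of -1.96, -4.68 and -2.90, and the mismatch repair gene MSH6 of -1.97, -2.63 and -2.24. At least 2-fold in each line were 321 of the rises and 259 of the falls. Of the 816 genes 11 also rose in p53KO HCT116, and 1 of the 1465 also fell there. Opposite calls were made for 256 genes between p53WT HCT116 and MCF7, 836 between p53WT HCT116 and SJSA and 1232 between MCF7 and SJSA. Without p53WT HCT116 DMSO replicate 1 the count of shared falls was 968.

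Under DMSO alone, 499 genes were higher in p53WT than in p53KO HCT116 and 347 were lower, or 821 and 588 with the replicate block. CDKN1A was higher at 142 ± 4.91 against 59.5 ± 16.4 CPM (1.25 ± 0.15), GDF15 by 2.56 ± 0.26, FAS by 1.35 ± 0.19 and DDIT4 by 1.62 ± 0.22, whereas MDM2 was at 0.17 ± 0.12 and did not pass (adjusted p = 0.601 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The largest differences lay outside the p53 lists. The transcription factor gene HNF1B was at 8.13 ± 0.308 CPM in p53WT cells and had 0 counts in p53KO cells (at least 164-fold higher against 3 counts over both libraries), and NRIP1 (9.30 ± 0.30), the stem cell marker PROM1 (6.93 ± 0.49), EHF (6.77 ± 0.27) and LAMA4 (6.71 ± 0.45) were also higher. Lower in p53WT cells were ANGPT2, which encodes angiopoietin-2 (-5.58 ± 0.31), TM4SF18 (-5.91 ± 0.45), the glucose transporter gene SLC2A3 (-3.62 ± 0.24) and DNER (-3.42 ± 0.40). Of 20 arrest targets 6 were higher and PLK2 and PTP4A1 lower (6 and 2 adjusted over the list alone). The set call (camera adjusted p = 0.0494) was lost with the replicate block (0.0528) and at an adjusted p = 0.621 with an estimated correlation. Of 22 metabolism and repair targets 5 were higher, among them SAT1 (0.84 ± 0.14), and 0 lower (8 and 1 adjusted over the list alone and with the block, camera adjusted p = 0.00938, and adjusted p = 0.391 with an estimated correlation), and of 22 apoptosis targets FAS and TNFRSF10C (5 and 1 adjusted over the list alone, 6 and 1 with the block). Of the G1/S, G2/M and homologous recombination lists only MCM6 was higher (0.35 ± 0.10) and PALB2 lower (-0.67 ± 0.12), and the MCM6 call was lost without any 1 of the 4 libraries, with upper-quartile scaling and after thinning (0.33 to 0.37). Adjusted over the list alone the counts were 0 and 0, 0 and 0, and 1 and 1, with the block 1 and 0, 0 and 0, and 1 and 1, and of the 32 G2/M genes 0 had an unadjusted p under 0.05 in edgeR and 0 passed in DESeq2. Without p53KO DMSO replicate 2 the counts were 266 higher and 180 lower, without p53KO DMSO replicate 1 they were 294 and 216, and without p53WT DMSO replicate 1 the lower count was 201.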

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

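The tests for mixed cells and for a stress response in p53KO HCT116, and the test for cells of another line in SJSA, were chosen after the result was seen. The results here drew attention because a test of the difference in Nutlin effect between lines passed the threshold. Between p53WT and p53KO HCT116 the effect was higher in p53WT cells for 666 genes and lower for 801, while RLE scaling gave 749 higher and 676 lower, upper-quartile scaling 774 and 660, and library totals 758 and 628. By gene the difference in log2 fold change was 5.09 for UNC5B-AS1, 5.04 for TP53I3, 4.53 for CEACAM1, 3.93 for CDKN1A, 3.84 for WDR63 and 3.72 for MDM2, and -2.77 for CCNE2, -2.72 for ZNF367, -2.41 for DTL, -2.20 for E2F2, -2.20 for WDR76 and -2.14 for FAM111B. Between MCF7 and p53WT HCT116, 4204 genes differed, with TBX4 at 8.37, MDM2 at 1.47, CDKN1A at 0.95 and TP53 at -1.09. Between SJSA and p53WT HCT116, 8013 genes differed, with TP53 at -0.64 and NXPH2 at -5.75, and between SJSA and MCF7 8028 differed, with TP53 at 0.45, CDKN1A at -0.57 and MDM2 at -1.09.

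A first pattern was the rise, in SJSA under Nutlin, of 967 of 7639 genes that had at most 3 counts in the DMSO libraries together, against 377 of 8406 in MCF7, 56 of 8250 in p53WT HCT116 and 0 of 8939 in p53KO HCT116. Most of these genes stayed at low levels. Under Nutlin the 967 genes had a median of 0.784 CPM, and 53 of them reached 5 CPM. In MCF7 the median was 0.378 CPM and 16 reached 5 CPM, and in p53WT HCT116 it was 0.241 CPM and 0 did. Reads from DNA or unspliced RNA were predicted to bring most silent genes above 3 counts under Nutlin. The shares that passed were 32.9% of them and 43.6% of the protein-coding ones. A low level of such reads could leave many genes at 3 counts or fewer, so these shares do not decide the question. They exceeded those elsewhere, at 14.6% in MCF7, 8.885% in p53WT HCT116, 8.894% in p53KO HCT116 and 8.19% in SJSA from Nutlin to DMSO. Of silent protein-coding genes in the other lines 11.4 to 19.5% passed. Their median count under Nutlin was 2 in SJSA, 1 in MCF7 and 0 in p53WT and p53KO HCT116. This source therefore stays open. Cells of another line are argued against by the levels. Of the 967 genes, 67.2% (650 genes, 95% exact binomial interval 64.2 to 70.2%) stood higher in SJSA under Nutlin than in any of the 6 groups of the other lines. This ranking was made largely at the low levels given above. Transcription running on from an upstream gene may account for part of the pattern. Among rising genes with 1 same-strand neighbour expressed under Nutlin it was the upstream one in 62.4% (231 against 139, exact binomial p = 1.99e-06), compared with 48.1% among silent genes that did not rise (Fisher's exact p = 4.46e-07). Genes of the pattern could themselves count as such neighbours. With neighbours expressed under DMSO the share was 58.8% (224 against 157, exact binomial p = 7.01e-04, Fisher's exact p = 1.78e-05). The strand setting of the counting is not given, which limits both tests. Under Nutlin neither neighbour was expressed for 226 of the 811 genes with annotated neighbours, so this leaves a share open. In MCF7 the test with neighbours expressed under Nutlin did not pass (57.0%, exact binomial p = 0.121). A p53 response specific to SJSA was not tested and stays open.

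A second pattern was the small response of p53KO HCT116, in which 19 of 24 risen genes also rose in p53WT cells. An admixture of p53WT cells as the whole cause is argued against by genes that rose 4-fold or more in p53WT cells. Of 276 such genes, the 102 with at least 5 CPM under Nutlin in p53WT cells were used. The p53KO cells showed a median of 1.87% of their gain (quartiles 0.315 and 4.996%), compared with 34.5% (quartiles 11.7 and 95.9%) for the 19 shared genes. These 19 genes were picked for having risen in p53KO cells, which raises their share by selection, so the 34.5% is not an independent reference. A share of a few percent stays open as part of it, since TP53, which such cells would bring, went from 8.64 and 8.10 CPM in the p53KO DMSO libraries to 10.9 and 11.3 CPM under Nutlin (0.41 ± 0.13, not past the threshold), and CDKN1A passed with the replicate block (adjusted p = 0.00339 in edgeR). A stress response that does not need p53 is a candidate explanation that could not be decided. Of 22 stress genes 20 lay above 0, but the list's adjusted p was 0.418 with an estimated correlation in camera.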

How the results depend on the processing

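Upper-quartile scaling, library totals and thinning were chosen after the results were seen. Apart from the counts given here, each comparison's count of called genes stayed within 1.5 times its value in every setting run. The cause was not tested except where a setting by its construction tests fewer libraries. In p53KO HCT116, 24 genes rose and 9 fell, but 77 and 46 in DESeq2, 112 and 73 without the filter, 69 and 55 with only the lines compared, and 40 rose with library totals. The replicate block gave 117 and 78 there, 1092 higher and 1328 lower for the difference between p53WT and p53KO HCT116, and 821 higher and 588 lower between them under DMSO. DESeq2 gave 1002 higher for the same difference. With library totals 1702 genes fell in p53WT HCT116. All 33 calls in p53KO HCT116 were kept in DESeq2 and with the block, 31 with RLE and 30 with only the lines compared. In p53WT HCT116 4821 of 4930 calls were kept in DESeq2 and 4712 with RLE, in MCF7 7509 and 7645 of 8502, and in SJSA 10113 and 10481 of 11728. Without 1 library at a time, with fewer libraries in the fit, p53WT HCT116 gave 1464 to 2071 rises and 1541 to 2226 falls, p53KO HCT116 2 to 15 and 3 to 5, and the 3 lines with intact TP53 together 968 to 1512 shared falls. The difference between p53WT and p53KO HCT116 gave 421 to 687 higher and 466 to 720 lower, and their DMSO groups 266 to 460 higher and 180 to 286 lower.

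The median log2 fold change of all genes in SJSA was -0.07 with TMM, 0.13 with RLE, 0.20 with upper-quartile scaling and -0.15 with library totals. For the difference from p53WT HCT116 it was -0.28 for SJSA and -0.17 for MCF7 with library totals, and 0.15 for SJSA with upper-quartile scaling. For SJSA against MCF7 it was 0.12 with upper-quartile scaling and -0.12 with library totals. Of the 870 values of named genes, 807 kept direction and side of the threshold in DESeq2, 859 with RLE, 823 without the filter, 794 with only the lines compared, 845 after thinning and 857 each with upper-quartile scaling and library totals. With the block 814 did, 55 more passed and 1 no longer did, while over all tested genes it kept 8430 of 8502 calls in MCF7 and made 9184, and kept 11662 of 11728 in SJSA and made 12312. Counts of list members in the report that it moved by over 1.5 times stand beside their results, smaller moves are not given, and it changed no set call of a list other than those given here. Over all left-out libraries 276 values lost their call, 33 gained one and 1 turned. The difference for CD79A between SJSA and p53WT HCT116 was 3.31, and -1.44 to 4.04 without 1 library, the lowest without p53WT DMSO replicate 1. CD79A had 9 and 0 counts in the p53WT DMSO libraries, so that setting left it at 0 counts in the group. Of 171 list tests 124 kept their side with an estimated correlation and 47 no longer passed. With the block 164 kept it. The stress list newly passed in SJSA, in the MCF7 to p53WT HCT116 difference and under DMSO (adjusted p = 0.0482, 0.0150 and 0.0248 in camera), as did the histone list in p53KO HCT116 (0.0346) and the NF-kB list in MCF7 (0.0280). Without the block these lists had an adjusted p of 0.597, 0.574, 0.732, 0.476 and 0.451 with an estimated correlation, in the same order. The arrest list no longer passed in the SJSA to p53WT HCT116 difference (0.0539) or under DMSO (0.0528). Depth limited genes with few counts. With 2 libraries per group, changes of 1.5-fold in genes above a minimum level were recovered in 49.3 to 61.2% of simulated cases in the Nutlin comparisons.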

Other observations

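The gene groups in the first 2 paragraphs were put together after the results were seen, while the test on basal p53 activity was set before its result was seen. Most of a group of genes of the epidermis and of stratified epithelia rose with Nutlin in the lines with intact TP53. Of 19 such genes 13 rose and 1 fell in p53WT HCT116, 16 rose and 1 fell in MCF7, and 13 rose and 1 fell in SJSA, whereas 0 were called in p53KO HCT116. The desmosomal cadherin gene DSC3 rose by 1.31 ± 0.18 in p53WT HCT116, 1.84 ± 0.57 in MCF7 and 1.05 ± 0.18 in SJSA. In MCF7 it stayed near the floor, at 0.127 CPM under DMSO and 0.472 under Nutlin (9 and 27 counts). COL17A1, which encodes a hemidesmosomal collagen, rose by 2.63 ± 0.34, 8.27 ± 0.46 and 0.98 ± 0.33, and the keratin gene KRT17 by 1.37 ± 0.28, 1.65 ± 0.22 and 0.85 ± 0.14. LAD1 rose from 0 counts in SJSA but fell in p53WT HCT116 (-0.36 ± 0.12) and MCF7 (-0.51 ± 0.12). Calls were lost for DSC3 in MCF7 without MCF7 DMSO replicate 1 (1.745) or MCF7 Nutlin replicate 2 (0.85), and for COL17A1 in SJSA without SJSA DMSO replicate 1 (0.71) or SJSA Nutlin replicate 2 (0.69). The LAD1 fall in p53WT HCT116 was lost with library totals (-0.25), upper-quartile scaling (-0.31) and without p53WT DMSO replicate 1 (-0.29) or p53WT Nutlin replicate 1 (-0.40) or 2 (-0.33). By camera the unadjusted p was 3.60e-08, 7.77e-10 and 2.33e-05 in these lines, and 0.00711, 0.00392 and 0.0249 with an estimated correlation. The difference between p53WT and p53KO HCT116 had a p of 1.19e-10, or 0.00302 with an estimated correlation, with 8 genes higher and 0 lower. Several of the 19 genes were put in the group because they rose here, so these p-values do not stand as independent evidence.

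In p53KO HCT116 the circadian repressor genes NR1D1, NR1D2 and BHLHE41 fell among 18 clock genes and 0 rose (camera unadjusted p = 0.00224, or 0.165 with an estimated correlation), and in the difference from p53WT HCT116 3 clock genes were higher in p53WT cells (0.00523, or 0.200 with an estimated correlation). The BHLHE41 fall was lost without p53KO DMSO replicate 2 (-0.94) or p53KO Nutlin replicate 2 (-1.001), and the NR1D1 fall without the latter (-1.33). NR1D2 also fell in p53WT HCT116 (-1.11 ± 0.15), with no difference past the threshold from p53KO cells (0.17 ± 0.21). NR1D1 fell there too (-0.61 ± 0.19), a call lost with library totals (-0.50), with only the lines compared (-0.57) and without p53WT DMSO replicate 2 (-0.05) or p53WT Nutlin replicate 2 (-0.54). The NR1D1 difference did not pass (0.74 ± 0.27, or 0.35 without p53WT DMSO replicate 1) but did with the replicate block (0.78), without the filter (0.76) and without p53WT DMSO replicate 2 (1.304). The BHLHE41 difference passed (1.19 ± 0.28), except without p53WT DMSO replicate 1 (0.91), p53KO DMSO replicate 2 (0.98) or p53KO Nutlin replicate 2 (1.04). In all 4 clock genes rose and 3 fell in p53WT HCT116, 3 and 2 in MCF7 and 6 and 5 in SJSA, with unadjusted p of 0.383, 0.353 and 0.968 in camera. Under DMSO 5 clock genes were lower in p53WT cells, among them CRY1 (-0.78 ± 0.17), CLOCK (-0.66 ± 0.13) and BHLHE41 (-1.88 ± 0.20), and 0 were higher (6.48e-05, or 0.0810 with an estimated correlation). The CRY1 and CLOCK calls were lost without p53KO DMSO replicate 2 (-0.60 and -0.55), CRY1 also without p53WT DMSO replicate 1 (-0.71) and CLOCK without p53WT DMSO replicate 2 (-0.58). The p53WT DMSO libraries stood far apart for several clock genes, such as PER1 (86.8 ± 46.7 CPM), NR1D1 (95.8 ± 44.2) and BHLHE40 (41.6 ± 30.2). They lay closer for others, such as CRY1 (13.0 ± 0.83) and CLOCK (61.0 ± 4.48). In the p53KO DMSO libraries PER2 was at 30.9 ± 12.1 CPM. Of 9 genes of zinc and metal binding, MT1E rose in p53KO HCT116 and the zinc exporter gene SLC30A1 fell (0.00769, or 0.132 with an estimated correlation). In p53WT HCT116 3 of the 9 rose and 0 fell (0.0411, or 0.235 with an estimated correlation), with MT1E at 1.07 ± 0.14 and no difference past the threshold from p53KO cells (-0.06 ± 0.19), whereas the effect on SLC30A1 was higher in p53WT cells (1.63 ± 0.26). In MCF7 2 of the 9 rose and 1 fell and in SJSA 3 rose and 0 fell, with SLC30A1 rising in both (1.17 ± 0.18 and 2.25 ± 0.18). The MCF7 replicates stood far apart for MT2A (117 ± 59.8 CPM under DMSO, 185 ± 126 under Nutlin) and MT1F (21.2 ± 15.2 and 51.7 ± 38.1). For SLC30A1 they lay closer (23.3 ± 5.11 and 52.2 ± 3.54). The clock and metal lists were put together after members were seen among the calls in p53KO HCT116, so their p-values are not independent evidence either. Among 459 tested zinc finger genes with ZNF symbols, 71 rose and 35 fell in p53WT HCT116, 67 rose and 78 fell in MCF7, 116 rose and 162 fell in SJSA, and 1 rose in p53KO HCT116. Camera gave an unadjusted p of 0.161, 0.777, 0.499 and 0.0194 in these lines, the last 0.144 with an estimated correlation. No shift of this group was thus shown in the lines with intact TP53.

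A further pattern was the difference between p53WT and p53KO HCT116 under DMSO. If p53 activity in untreated p53WT cells set it, the genes should move the same way with Nutlin in MCF7 and SJSA. Of the 499 genes higher in p53WT cells 20.2% rose in both lines (101 genes, 95% exact binomial interval 16.8 to 24.0%), against 10.3% of all tested genes (Fisher's exact p = 2.27e-11) and 34.6% of the genes that rose with Nutlin in p53WT HCT116, so basal p53 activity may account for part of them. Of the 347 genes lower in p53WT cells 14.4% fell in both lines (95% exact binomial interval 10.9 to 18.6%), against 16.1% of all tested genes and 57.0% of the Nutlin genes. The predicted excess was thus not found for that direction. The Nutlin genes include all 32 G2/M genes, of which 0 were called under DMSO. Genes lowered by basal p53 activity need not resemble them, so this does not decide the question. However, 16.14% of these 347 genes (56 genes) rose in both lines, against 10.3% of all tested genes. An excess of risen genes was thus not confined to the direction that basal p53 activity predicts. The 20.2% above is therefore not specific to it, and the part it may account for is not settled. Divergence between the cell clones was not tested and stays open for both.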
